A study of Mus musculus with 2 samples.

How the data were processed

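CD5-positive gamma delta T cells from the spleens of wildtype mice and of mice carrying the LAT3YF allele were compared on 2-colour expression arrays. Per the labels, the cells were isolated with anti-CD5 magnetic beads and a FACSDiva sorter, and total RNA was hybridised. The series holds 2 arrays, each carrying both populations, 1 population per channel, with the dyes reversed between the arrays. The labels call these the + polarity and the - polarity ratio profile. Nothing in the labels gives separate animals or RNA extracts for the 2 arrays, so the pair was counted as 1 replicate of the comparison, and the difference between LAT3YF and wildtype has no replicate check. Errors given as an SD are over the 2 arrays and cover technical error only.

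The deposited table holds 1 log ratio of the 2 channels per probe and array, made by the authors. It was read as log10, a choice fixed before the data were examined, because neither the labels nor the table gives the base of the logarithm. The scanner, image analysis, background correction, normalization and numerator of the ratio are not given in the sources used here. The deposited log10 ratios had a median of -0.00284 on the + polarity array and 0.00101 on the - polarity array, so the values were already centred near 0. Intensities, detection calls and background were not analysed here, so low signals could not be told from high ones, and the number of arrays limits the precision.

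Of 8014 probes, all measured on both arrays, 4654 had 1 gene in the platform annotation, 73 had several and 3287 had none listed. Gene identifiers of 4640 of the single-gene probes were found in the RefSeq gene table (GRCm38.p6), and none of their symbols needed updating. Probes with several genes or none were left out of gene-level results. The value of a gene was the mean over its probes, which gave 4331 genes, 294 of them with more than 1 probe. Among those, the median range between probes of a gene was 0.0878, and 0 genes had probes past 2-fold in opposite directions. Probes for close relatives in a family, such as the Ly49 receptors (Klra) and the receptor and immunoglobulin gene segments, can share signal, and their gene assignment is uncertain. No genome build is named with the values, so no coordinates are given.

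The deposited columns correlated negatively (Pearson r = -0.301, Spearman rho = -0.154, across probes, which are not independent replicates), as ratios of dye-reversed arrays do before their sign is turned. The - polarity array was therefore turned (multiplied by -1) and the 2 arrays were averaged, which cancels a dye effect that is alike on both arrays. In the averaged values a positive sign stands for 1 of the 2 populations throughout and a negative sign for the other. Per the labels, channel 1 held wildtype and channel 2 LAT3YF on the + polarity array, and the reverse on the - polarity array. The labels name neither the dyes nor the numerator of the ratio, so which sign belongs to LAT3YF was left open.

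A gene was called when its mean log10 ratio was at least 2-fold in size (0.301 on the log10 scale) and had the same sign on both arrays after turning. This is a rule of size, not a test. Its error was gauged from the dye component, the part of each gene's ratio that changed sign between the arrays after turning: genes with opposite turned signs and a dye component past 2-fold were counted in the same way. A total of 27 gene lists were fixed before the data were examined. For the 26 lists with at least 3 measured genes, the median log10 ratio was placed among the medians of 10000 random lists of the same size from all named genes. A list was said to stand apart when its median lay outside the central 95% of these. Random lists could not be matched on expression, because no intensity was used, and they take genes as independent, so the percentiles describe these arrays and test no condition. The tail share of a list is the two-sided share of random lists at least as extreme. Its Benjamini-Hochberg adjustment over the lists left the same number of lists apart, 16, in the main setting.

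Genes named in the text were chosen by a rule fixed beforehand. On each side these were the 15 genes with the largest value of the smaller of their 2 array ratios. Also named were up to 4 called members per list and side, up to 3 members of lists without a called gene, Lat and Cd5. Unnamed probes were limited to 2 per side. Il4, Il5, Junb, Maf, Rora, Klra7, Klrc2, Pf4, Cd4, the CD3 chain genes and heat shock genes in the report lie outside this rule. They were chosen after their values were seen.

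The rule was tested on simulated data for this comparison, with 4331 genes, 200 of them changed and errors of the size of the observed dye component. It recovered 52% of genes changed 2-fold, 91.5% of those changed 3-fold and 99.5% of those changed 5-fold, and it called between 184 and 187 unchanged genes. Alternatives were a threshold of 1.5-fold or 3-fold, centred or scaled arrays, other log bases, other rules on sign, probes in place of genes, each array alone, the mean of a list in place of its median, and limma's moderated test over the 2 arrays. Random lists matched on expression were planned and not run. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.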

Results

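The transcripts of CD5-positive gamma delta T cells from LAT3YF and wildtype mouse spleens were compared on a pair of dye-reversed arrays. LAT is the adaptor that couples the T cell receptor to its signalling enzymes, and the 3YF name denotes tyrosine-to-phenylalanine replacements in it. CD5 is a surface glycoprotein of T cells that was used here to isolate the cells. The comparison asks which transcripts differ in abundance between gamma delta T cells with the mutant and with the normal adaptor. Ratios are given as the mean log10 ratio ± SD of the 2 arrays, with the fold in brackets. Positive values mark transcripts more abundant in 1 population and negative values those more abundant in the other. Which sign is LAT3YF is not given in the sources used here, so each statement below can be read with the populations exchanged. Folds assume base 10, and if the deposited values were log2 the largest gene ratio, 19.6-fold, would be 2.45-fold.

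On this unreplicated pair of arrays, the populations differed in genes of type 2 responses, of cell division, of macrophages and of killer cell receptors. On the positive side lay the cytokine genes Il6, Il13 and Csf1, the transcription factor gene Gata3, the granzyme gene Gzmb and many genes of cell division. On the negative side lay the CD8 chain genes Cd8a and Cd8b1, the cytokine gene Il22, most measured NK cell receptor genes and genes of splenic macrophages such as Adgre1, Vcam1 and Spic. Of 4331 genes, 379 (8.75%) differed at least 2-fold with the same sign on both arrays, 161 of them positive and 218 negative. By comparison, 181 genes had opposite signs and a dye component past 2-fold, which gauges technical error at this threshold. In simulated data the rule called between 184 and 187 unchanged genes. The simulated errors were set to the size of the dye component, so that count is no separate gauge. The dye component also holds any dye effect of a gene that is alike on both arrays and cancels in the mean. Both counts may therefore overstate the error of the mean. Single arrays gave 742 genes past 2-fold (- polarity) and 452 (+ polarity). The count was 774 at 1.5-fold and 144 at 3-fold, and it would be 17 if the values were log2 and 62 if they were natural logs. Where each array was past 3-fold on its own, 112 genes had the same sign and 5 had opposite signs. The 2 arrays count as 1 replicate, so no test of the conditions was made. Limma's moderated test over the 2 arrays measures only the spread between them. In it, 0 genes passed a Benjamini-Hochberg adjusted p of 0.05, and 791 of 4331 had an unadjusted p under 0.05. The test had 1 residual degree of freedom per gene and so little power, and its 0 does not show that the arrays disagree.

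**Figure D1:**
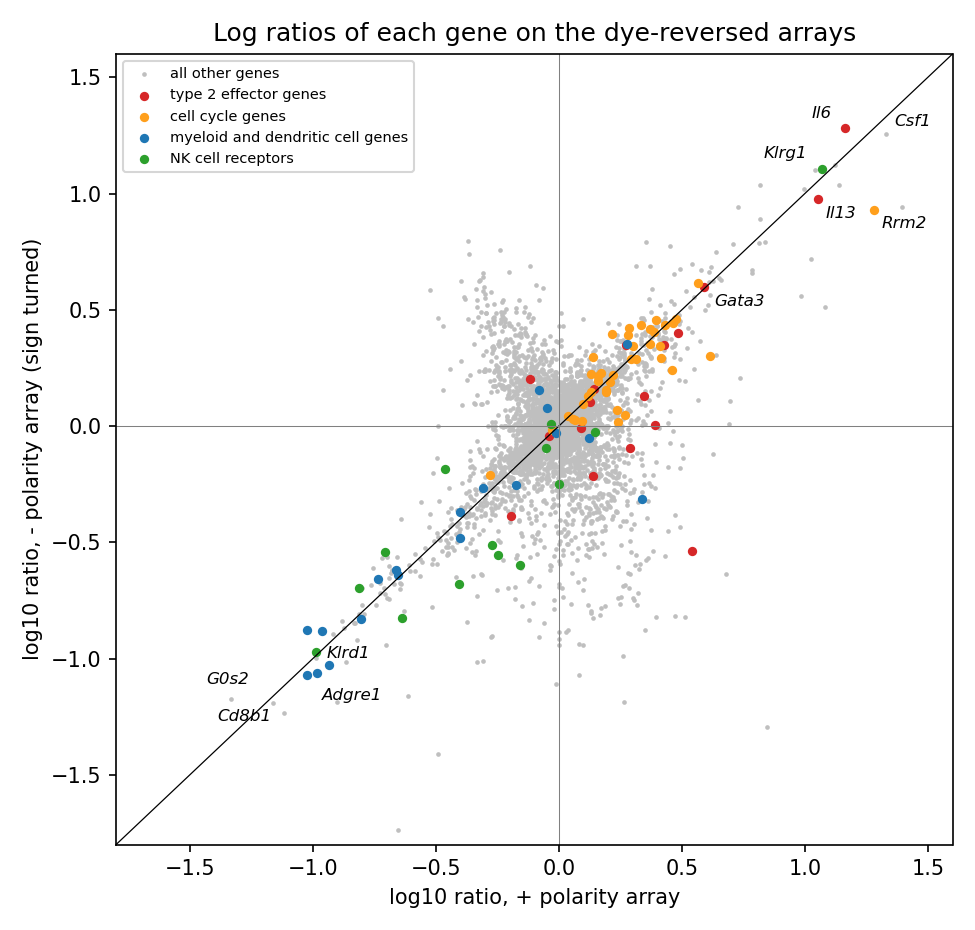
Log10 ratio of each of the 4331 genes on the + polarity array (horizontal axis) and on the - polarity array after its sign was turned (vertical axis); each point is 1 gene, coloured for 4 gene lists, and the black line marks equal values. Genes with large ratios such as Il6 (1.22) and Adgre1 (-1.05) lie near the line, and a second arm at right angles to it holds genes whose ratio followed the dye.

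The 15 leading genes on the positive side had ratios from 6.32-fold to 19.6-fold. Csf1, the macrophage growth factor, had the largest value at 1.29 ± 0.052 (19.6-fold). Il6, an inflammatory cytokine, followed at 1.22 ± 0.083 (16.7-fold). Cysltr1, a cysteinyl leukotriene receptor, was at 1.17 ± 0.32 (14.8-fold), and Ptgir, the prostacyclin receptor, had a log10 ratio of 1.12 on each array (13.2-fold). Klrg1, an inhibitory receptor of effector lymphocytes, was at 1.09 ± 0.025 (12.2-fold). Rrm2, a subunit of ribonucleotide reductase, was at 1.11 ± 0.25 (12.7-fold). Bace2, an aspartic protease, was at 1.09 ± 0.071, and Cntn1, a neural adhesion molecule, at 1.07 ± 0.042. The T cell receptor segment Trbv1 was at 1.01 ± 0.018 (10.2-fold). Tnfsf13b, the B cell survival factor BAFF, was at 0.928 ± 0.15 (8.47-fold). Gzmb was at 0.854 ± 0.053 (7.14-fold), the carbohydrate-binding gene Stbd1 at 0.835 ± 0.15 and Cish, a feedback inhibitor of cytokine signalling, at 0.814 ± 0.032. The chemokine gene Ccl1 completed the group at 0.801 ± 0.020 (6.32-fold). Il13, also in this group, is given with the type 2 genes.

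The 15 leading genes on the negative side had ratios from 7.26-fold to 17.9-fold. G0s2, an inhibitor of lipolysis, was at -1.25 ± 0.11 (17.9-fold). Cd8b1, the CD8 beta chain, was at -1.18 ± 0.082, and Slc40a1, the iron exporter ferroportin, was at -1.17 ± 0.021 (14.9-fold). Adgre1, a surface receptor of macrophages, was at -1.05 ± 0.035 (11.2-fold). Clec1b was at -1.04 ± 0.20, the adhesion molecule Vcam1 at -1.02 ± 0.058 and the niacin receptor Hcar2 at -0.993 ± 0.0081. Mrc1, the macrophage mannose receptor, was at -0.982 ± 0.066 (9.60-fold). Klrd1, which encodes the NK receptor chain CD94, was at -0.979 ± 0.012 (9.52-fold). Cd14 was at -0.950 ± 0.10, and Il22, an epithelial-acting cytokine, was at -0.940 ± 0.11 (8.70-fold). Spic, a transcription factor of red pulp macrophages, was at -0.922 ± 0.058 (8.36-fold). Ly6c1 was at -0.908 ± 0.016, Plac8 at -0.871 ± 0.0046 and the protease inhibitor Slpi at -0.861 ± 0.030.

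Genes of type 2 responses lay on the positive side. Of 17 measured genes in this list, 6 were called positive and 0 negative, and the list's median log10 ratio of 0.152 lay above the central range of random lists (-0.0599 to 0.0652). It was 0.288 on the + polarity array alone and 0.130 on the - polarity array alone, and stood apart on each. Il13 was at 1.01 ± 0.055 (10.3-fold), Gata3, the master transcription factor of type 2 T cells, at 0.593 ± 0.0057 (3.92-fold) and Irf4 at 0.443 ± 0.059 (2.77-fold). Il6, the largest of the 6, is an inflammatory cytokine made by many cell types. Of the 17 measured genes, 14 had a mean above 0 and 3 below 0. The lowest, Junb, was at -0.289 ± 0.14 and was not called. Among members that were not called and were named after their values were seen, Il4 was at 0.198 ± 0.27, less than its spread between the arrays, and Il5 at 0.237 ± 0.15, below the threshold. Of the 19 measured genes of type 1 and cytotoxic responses, 3 were called positive (Gzmb, Ccl5 at 0.391 ± 0.021 and Fasl at 0.320 ± 0.0093) and 0 negative. That list did not stand apart by its median (-0.0148), while its mean was positive (0.0785) and stood apart only before adjustment over the lists (adjusted tail share 0.0685).

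Genes of interleukin-17-producing and innate-like gamma delta T cells lay mainly on the negative side. Of 11 measured, 4 were called negative and 1 positive, with a median of -0.240 below the central range of random lists (-0.0773 to 0.0828). Il22 led, followed by Ahr, a ligand-activated transcription factor, at -0.613 ± 0.013 (4.10-fold), the chemokine receptor Ccr6 at -0.480 ± 0.077 (3.02-fold) and Il17a at -0.479 ± 0.32 (3.01-fold), which was -0.252 and below 2-fold on the + polarity array. Sox13, a transcription factor of gamma delta T cells, went the other way at 0.465 ± 0.034 (2.92-fold). Maf (0.115 ± 0.017) and Rora (0.131 ± 0.012) also had positive means but were not called, and 8 of the 11 means were below 0. Of 14 measured NK cell receptor genes, 9 were called negative and 1 positive, with a median of -0.385. It was -0.260 on the + polarity array alone and -0.526 on the - polarity array alone, and stood apart on each. Some of the 9 were below 2-fold on 1 array, such as Klra7 (-0.16, + polarity) and Klrc2 (-0.183, - polarity). After Klrd1 came Klrb1c, which encodes NK1.1, at -0.755 ± 0.081 (5.69-fold), Klra1 at -0.731 ± 0.13 and Klrc1, which encodes NKG2A, at -0.624 ± 0.12. The positive gene was Klrg1. Myeloid and dendritic cell genes lay on the same side as both groups, with a median of -0.442.

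Genes of cell division lay on the positive side. Of 41 measured, 18 were called positive and 0 negative, 39 had a mean above 0, and the median was 0.219 (1.66-fold). After Rrm2, the largest were the mitotic kinase Nek2 at 0.590 ± 0.037 (3.89-fold), the proliferation antigen Mki67 at 0.467 ± 0.011 (2.93-fold) and Hells at 0.457 ± 0.22 (0.302 on the - polarity array). Genes of energy and lipid metabolism and of protein turnover also had positive medians. Of 12 measured glycolysis genes, 11 had a mean above 0 with a median of 0.191, and 1 was called, Tpi1 at 0.427 ± 0.039 (2.67-fold). Of 10 measured genes of cholesterol and fatty acid synthesis, 2 were called positive, Stard4 at 0.484 ± 0.0072 and Lss at 0.307 ± 0.062, with a median of 0.141. The 2 probes of Stard4 gave 0.340 and 0.628. None of the 14 measured genes of oxidative phosphorylation was called, but their median was 0.114, led by Ndufa2 at 0.163 ± 0.027, Cox8a at 0.162 ± 0.012 and Cox6a1 at 0.159 ± 0.028. None of the 21 measured proteasome genes was called either, with a median of 0.0995 and 20 means above 0, led by Psmb5 at 0.210 ± 0.040, Psmb9 at 0.193 ± 0.011 and Psmb8 at 0.184 ± 0.030. Of 27 cytoskeleton and motility genes, 6 were called positive and 0 negative, among them Lgals1 at 0.419 ± 0.032, Vim at 0.415 ± 0.056, S100a11 at 0.403 ± 0.030 and S100a10 at 0.322 ± 0.035, with a median of 0.0863. After adjustment over the lists, the calls were lost with the + polarity array alone for the cholesterol list (median 0.109, adjusted tail share 0.0549) and the proteasome list (0.0702, adjusted tail share 0.0676), and with the mean in place of the median for oxidative phosphorylation (0.0954, adjusted tail share 0.0673).

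**Figure D2:**
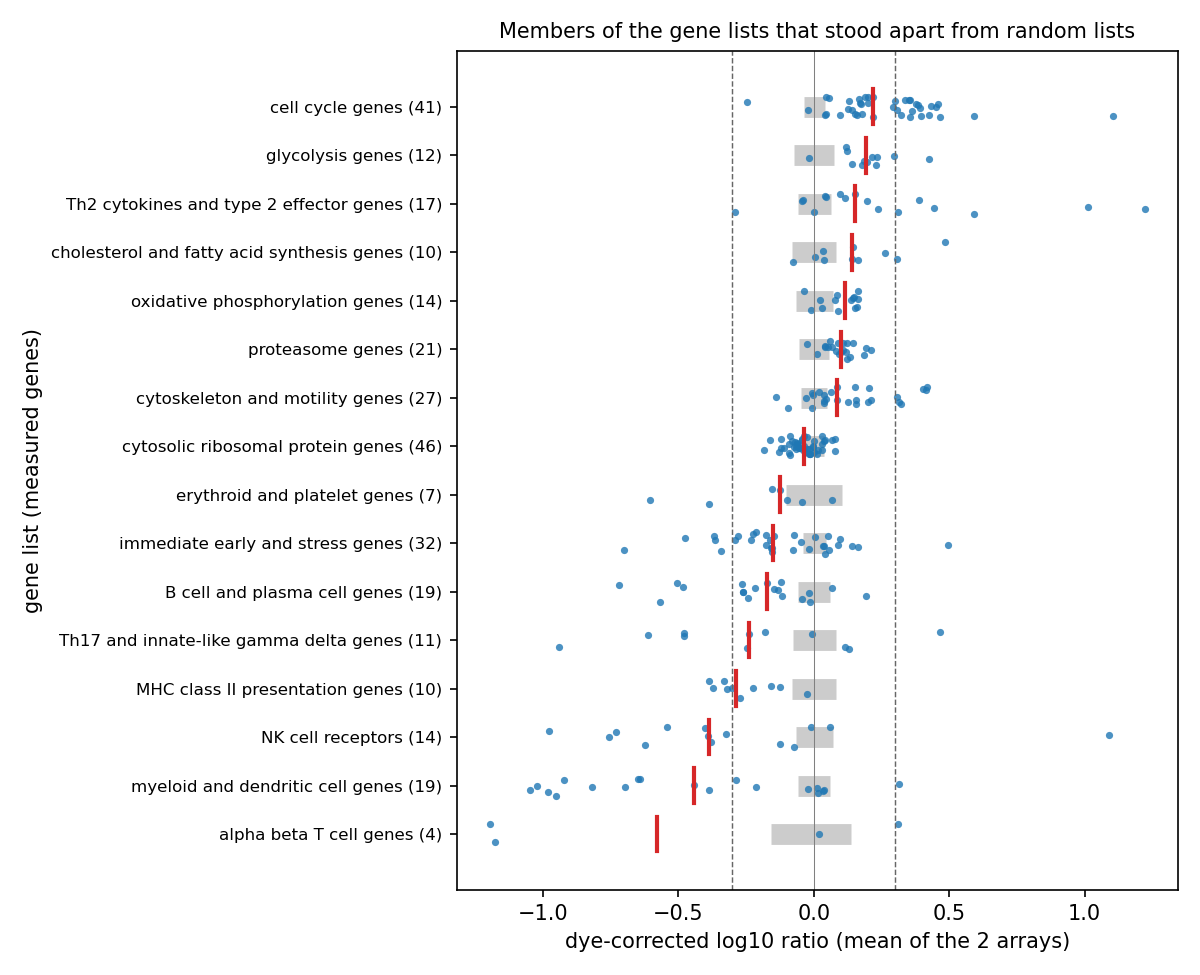
Dye-corrected log10 ratio (horizontal axis) of the measured genes in each of the 16 lists that stood apart from random lists, 1 blue point per gene; the red bar is the list's median, the grey bar the central 95% of medians of random lists of that size, and the dashed lines mark 2-fold. The cell cycle list (median 0.219) lies almost wholly above 0, and 14 of 19 myeloid genes lie below 0.

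Markers of several other spleen cell types, though not of stromal cells, lay mainly on the negative side. Of 19 measured myeloid and dendritic cell genes, 11 were called negative and 1 positive, with a median of -0.442 (2.77-fold). The 4 largest, Adgre1, Vcam1, Mrc1 and Cd14, are given above, and the positive gene was the chemokine receptor Ccr2 at 0.315 ± 0.052 (2.07-fold). Of 19 measured B cell and plasma cell genes, 4 were called negative and 0 positive, with a median of -0.174. These were Ighm, the immunoglobulin mu chain, at -0.719 ± 0.031 (5.23-fold), Cd72 at -0.568 ± 0.024, Blnk at -0.505 ± 0.069 and Cd79b at -0.482 ± 0.065. The other 15 were not called, and of the 19 B cell genes 17 had a mean below 0 and 2 above. Of 10 measured genes of MHC class II presentation, 5 were called negative and all 10 had a mean below 0, with a median of -0.288. H2-DMb1 was at -0.385 ± 0.0098 and H2-Ob at -0.372 ± 0.28 (-0.174 on the + polarity array), followed by H2-Eb1 at -0.331 ± 0.013 and H2-Aa at -0.319 ± 0.087. Of 7 erythroid and platelet genes, 2 were called negative, Epor at -0.604 ± 0.057 and Hba-a1 at -0.388 ± 0.0043. That list's median of -0.125 no longer stood apart with the + polarity array alone (-0.0761) and was -0.385 on the - polarity array. The median of -0.125 is the value of Pf4 (SD 0.59), whose ratio had opposite signs on the arrays (0.294 and, after turning, -0.543). Of 8 stromal and endothelial genes, 1 was called positive, Cxcl13 at 0.305 ± 0.095, and the median was 0.00759. The sort on CD5 was meant to leave these cell types out, apart from B cells that carry CD5.

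T cell identity genes gave mixed values. Lat, the mutated gene itself, was at 0.179 ± 0.010 (1.51-fold), below the threshold, and a change of its codons would not show in this ratio. Cd5, the gene of the sorting marker, was at 0.614 ± 0.0077 (4.11-fold). Cells of both populations were isolated through this molecule, and what the isolation did to the ratio was not tested. Of 27 measured genes of T cell receptor signalling, 2 were called positive, Cd5 and its relative Cd6 at 0.402 ± 0.079, and 1 negative, the Tec-family kinase Txk at -0.568 ± 0.0056 (3.70-fold). The list's CD3 chain genes Cd3d (-0.00738 ± 0.0063), Cd3e (0.110 ± 0.10), Cd3g (0.0954 ± 0.025) and Cd247 (-0.185 ± 0.13) were not called. The list's median was 0.00042. Of 4 measured genes of alpha beta T cells, Cd8a at -1.20 ± 0.77 (-0.654 on the + polarity array) and Cd8b1 were called negative and Zbtb7b, which directs T cells to the CD4 lineage, positive at 0.311 ± 0.075. Cd4 was at 0.0177 ± 0.047. The median was -0.579, and -0.301 on the + polarity array alone. It falls in the gap between the CD8 chain genes and Cd4 and Zbtb7b, so it describes no single gene. Which cells the CD8 chain transcripts came from was not tested. The T cell receptor beta segment Trbv1, given above, is outside the list and lay on the positive side. None of the constant-region genes of the gamma delta receptor in the list was measured by a named probe.

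The list of immediate early and stress genes had a negative median of -0.150, with 5 of 32 called negative and 1 called positive. Its heat shock genes, singled out after their values were seen, mostly had small positive ratios that were not called, such as Hspa1a at 0.164 ± 0.039 and Hsp90aa1 at 0.140 ± 0.037, while Dnajb1 was at -0.0715 ± 0.050. Rgs2 was at -0.701 ± 0.036 (5.03-fold), Klf4 at -0.476 ± 0.036, Gadd45a at -0.366 ± 0.039 and Nfkbiz at -0.364 ± 0.024, whereas Ier3 was at 0.496 ± 0.056 (3.13-fold). The myeloid genes lay on this side too (median -0.442). None of 46 cytosolic ribosomal protein genes was called. Their median was -0.0373, led by Rpl3 at -0.182 ± 0.079, Rps15a at -0.163 ± 0.045 and Rps4x at -0.126 ± 0.012, and it did not stand apart with the - polarity array alone (-0.0307) or when the mean replaced the median (-0.0376).

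The other lists did not stand apart by their medians. With the + polarity array alone, the regulatory (0.162), activation (0.0973), chemokine and adhesion (0.0733) and apoptosis (0.0677, adjusted tail share 0.0502) lists did, on the positive side. With means in place of medians, the naive (-0.178) and apoptosis (0.101) lists did. Among 16 T cell activation and inhibitory receptors, the costimulatory receptor genes Tnfrsf4 (0.650 ± 0.046, 4.47-fold), Tnfrsf18 (0.424 ± 0.0033) and Icos (0.340 ± 0.017) were called positive and Lag3 (-0.318 ± 0.030) negative, with a median of 0.0385. Tnfrsf4 and Tnfrsf18 were also the 2 called genes among 8 measured regulatory T cell genes, whose median was 0.00355. Among 8 naive and lymphoid-homing genes, Cd24a (-0.651 ± 0.040, 4.48-fold) and the homing receptor Ccr7 (-0.478 ± 0.23, with -0.317 on the + polarity array) were called negative, with a median of -0.0572. Of 33 genes of chemokines, their receptors and adhesion, 5 were called positive, including Ccl1, the integrin chain Itgb1 (0.522 ± 0.016) and the follicle-homing receptor Cxcr5 (0.405 ± 0.032). A further 4 were called negative, namely Ccr6, Ccr7, Ccr9 (-0.434 ± 0.46, only -0.106 on the + polarity array) and Ccl6 (-0.421 ± 0.029), and the median was 0.0278. Of 34 genes of cytokine signalling, Cish and Socs1 (0.348 ± 0.00064) were called positive and Id3 (-0.390 ± 0.037) and Ifngr1 (-0.380 ± 0.020) negative, with a median of 0.00104. Of 26 apoptosis genes, 5 were called positive, including Apaf1 (0.395 ± 0.0083), Casp1 (0.395 ± 0.033), Birc5 (0.394 ± 0.013) and Tnfsf10 (0.357 ± 0.039), with a median of 0.0286. Of 25 interferon-induced genes, Ly6c1 and Irf8 (-0.457 ± 0.0044) were called negative, with a median of -0.0417. That median was 0.00926 on the + polarity array alone and -0.0295 on the - polarity array alone.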

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

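All alternatives given here were planned before the data were examined. Random lists matched on expression were also planned and were not run, because no intensity was used; signal over background therefore limits the values to an unknown extent. Of the 379 called genes (161 positive, 218 negative), 376 were called with the same sign with the arrays centred on their medians and 369 with the arrays also scaled to the same spread, and the positive share moved from 42.5% to 43.4% and 44.6%. The count followed the threshold, with 774 genes (365 positive, 409 negative) at 1.5-fold and 144 (48 and 96) at 3-fold. It followed the log base too, with 17 genes (10 and 7) if the values were log2 and 62 (22 and 40) if natural logs, so folds and counts rest on the base while signs and ranks do not. Single arrays gave 452 to 742 genes (228 to 306 positive, 224 to 436 negative), the higher count from the - polarity array alone. Probes in place of genes gave 611 (252 and 359). Limma's adjusted p gave 0 genes, 0 positive and 0 negative, with 1 residual degree of freedom per gene and so little power. The correlation of the deposited columns, -0.301, was -0.391 over probes with 1 gene and -0.126 without the most extreme 1% of values at each end; the cause was not tested. Of 26 lists, 16 stood apart by the main rule and 15 to 19 under the 4 list alternatives (15 or 16 after Benjamini-Hochberg adjustment), with no list that stood apart changing sides, and 94 of 104 list values kept their call. With the mean in place of the median, the type 1 and cytotoxic (0.0785, not after adjustment), naive (-0.178) and apoptosis (0.101) lists also stood apart and the ribosomal list (-0.0376) did not. Over the arrays taken singly, medians ran from -0.0617 to 0.162 for the regulatory list, 0.0304 to 0.0973 for activation receptors, 0.0421 to 0.0733 for chemokines and adhesion, 0.0193 to 0.0677 for apoptosis, -0.385 to -0.0761 for the erythroid list and -0.0553 to -0.0307 for ribosomal proteins, each on the other side of the call with 1 array; the cause was not tested. For the 30 leading genes, Lat and Cd5, 160 values were compared under single arrays, centring, scaling and the largest probe. Of these, 155 moved by no more than the SD of the 2 arrays, 5 moved more and 0 changed sign. Single-array values cannot move by more than that SD by construction, and these genes have the same sign on both arrays. Each of these genes has 1 probe, so the largest-probe values equal the main ones. Only centring and scaling could have given larger moves, and all 5 came from there. No paired analysis was possible because the 2 arrays hold a single comparison and each already pairs both populations.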

Other observations

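The tests on gene families, on myeloid against B cell and stromal genes and on the neighbours of the NK receptor cluster were chosen only after the results were seen, and the cluster's bounds were changed after a first result; the tests on further macrophage genes and on the neighbours of Lat were written after the gene lists had been examined and before their own results were seen. Single genes are named here outside the rule for named genes and were chosen after their values were seen, except those that the report also names. All 90 families of at least 6 measured genes with a shared symbol stem were compared with random lists, and 3 stood apart after Benjamini-Hochberg adjustment over the families. Genes of tumour necrosis factor ligands lay on the positive side, with a median of 0.263 over 8 genes, 4 called positive and 0 negative, and 2 of the 8 were in a fixed list. After Tnfsf13b these were Tnfsf9, the ligand of 4-1BB, at 0.402, Tnfsf10 at 0.357 and Tnfsf11, the ligand RANKL, at 0.307. Kruppel-like transcription factors lay on the negative side, with a median of -0.162 over 13 genes, 4 of them in a fixed list, and 3 called negative, Klf15 at -0.647, Klf4 at -0.476 and Klf7 at -0.317. The myeloid list lay on this side too (median -0.442). The Ly49 receptor genes had a median of -0.286 over 11 genes, 4 of them already in the fixed NK receptor list. Among the 11, 5 were called negative, including Klra10 at -0.540 ± 0.043 and Klra6 at -0.673 ± 0.48 (-0.331 on the + polarity array). Probes without a listed gene also had large ratios. Of 3287, 76 were called positive and 126 negative, among them probe 638353 at 1.53 ± 0.14 (34.0-fold) and probe 637484 at 1.40 ± 0.0014, and probe 638351 at -1.36 ± 0.037 and probe 638071 at -1.02 ± 0.0085. The gamma chain segment Trgv1 was at -0.061 ± 0.025.

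Macrophage genes on the negative side are unusual for cells sorted as gamma delta T cells. A candidate explanation is that macrophages passed the sort with the population on that side. It was tested on 40 measured macrophage transcripts outside the fixed lists, most of them not looked at before: their median was -0.117, below all of 10000 random lists, with 16 called negative (Ctsl at -0.571, Ctsh at -0.535 and Timp2 at -0.502 among them) and 0 positive, while 8 neutrophil and granule genes, 4 of them also in the myeloid list, had a median of 0.0135 with 1 called negative (Fpr2 at -0.490). The median is on the side that carried-over macrophages would give, but 24 of the 40 were not called, among them Axl (-0.0704 ± 0.037), Msr1 (-0.0503 ± 0.051) and, with opposite signs on the arrays, Mertk (-0.0762 ± 0.17), Trem2 (-0.0856 ± 0.20) and C3ar1 (-0.0234 ± 0.22), 6 had means above 0, led by Cd80 (0.206 ± 0.062) and C5ar1 (0.189 ± 0.018), and how many of the 40 T cells express was not computed. Against a smaller share of T cells that raises all other cell types alike, the stromal list (0.00759) lay apart from the myeloid list by -0.450 (exact permutation p = 0.00995, two-sided). Stromal genes near background would not move, however. The myeloid and B cell medians differed by -0.269 (permutation p = 0.0672, two-sided). The erythroid median, -0.125, is the value of Pf4, whose sign differed between the arrays after turning. Both permutations take genes as independent within 1 unreplicated comparison, so they describe these arrays and test no condition. None of the CD3 chain genes was called, and a change of T cell share below 2-fold would not be called either. A smaller share of T cells therefore stays open, as does an untested difference in the gamma delta cells themselves between LAT3YF and wildtype.

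NK receptor genes on the negative side lie mostly in a cluster on 1 chromosome that differs between mouse strains, so a stretch of another strain's chromosome might move them together. Of the cluster's 43 measured neighbours that encode no such receptor, 6 were called (14.0%) against 8.45% of other genes (Fisher's exact p = 0.176, two-sided): Clec1b (-1.04 ± 0.20), Ltbr (-0.658 ± 0.034), Lag3 (-0.318 ± 0.030) and Cd9 (-0.495 ± 0.58, only -0.0817 on the + polarity array) were negative, and Tpi1 (0.427 ± 0.039) and Cdca3 (0.314 ± 0.11) positive. A first run took in Klrg1 and Klra16, which the gene table places away from the cluster, and so counted 228 neighbours over much of the chromosome, of which 18 were called (7.89%), no more than elsewhere. The bounds were then narrowed, so the answer depends on a choice made after that result, and the explanation stays open. A difference between the populations in the share of gamma delta cells that carry NK receptors, or NK cells in the sort, was not tested. The CD5 sort was meant to remove NK cells, which lack CD5, but a carry-over like that considered for macrophages could apply to them too. Ncr1 (-0.0723) and Il2rb (-0.0112), which NK cells express, were not called. Without intensities, genes near background cannot be told from unchanged ones, so these values do not settle it.

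A stretch of another strain's chromosome around the targeted Lat gene might likewise remain in the mutant. Of the 40 measured genes nearest to Lat, 4 were called (10%) against 8.76% elsewhere (Fisher's exact p = 0.776, two-sided), so no excess was detectable with this number of genes, and a small one stays open. Of the 4, Rgs10 at -0.810 ± 0.0042 and Itgax at -0.649 ± 0.0097 had the largest ratios, and Itgax is also among the myeloid genes.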
